A study of Homo sapiens with 8 samples.

How the data were processed

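Total RNA from U2OS cells, a human osteosarcoma line, was sequenced in 8 libraries that formed 4 groups of 2 replicates. The groups crossed 2 U2OS derivatives, U2OS-Flp-In-TREx (called Flp-In from here on) and U2OS AsiSI (called AsiSI), with a control siRNA (siNC) or an siRNA against MEPCE (siMePCE), the enzyme that caps 7SK RNA. Per the labels, siRNA was given in 2 rounds at 0 and 48 h and cells were lysed at 96 h. AsiSI cells received 300 nM 4-OHT for 4 h from 92 h. The labels do not state 4-OHT for Flp-In cells, so cell line and 4-OHT cannot be separated. They also do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries.

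Per the labels' protocols, libraries were made with a directional kit after removal of ribosomal RNA. The submitters' processing notes name Trim Galore, FastQC, STAR, SAMtools, featureCounts and the build hg19, without versions. The authors deposited raw counts for 80311 genes with hg19 coordinates. In all 80311 rows the listed length equals the distance from start to end, so each gene was counted as 1 interval with its introns. A nested gene never exceeded its host in any library in 3529 of 3529 same-strand pairs and 6890 of 6890 opposite-strand pairs with mean counts of at least 20. From these values, reads appear to have been given to every overlapping gene without regard to strand, a setting not given in the sources used here. Antisense, nested and overlapping genes can therefore not be told apart, and library totals hold some reads more than once. Genes overlap here if their coordinates touch at any length. Ratios compare their total counts, so the number of reads in common is not known. Histone genes and other near-identical copies are likewise uncertain as single genes. Symbols were present for 50.8% of rows, which held 85.2% of counts; gene types came from GENCODE 29 by identifier. All 8 columns of counts were used.

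Genes were kept with edgeR's filterByExpr by group, which left 43321. Counts were scaled by TMM and fitted as 4 group means over the 8 libraries with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. The 5 contrasts were siMePCE against siNC in each line, the average of both, their difference (AsiSI minus Flp-In), and AsiSI against Flp-In under siNC. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors (SE) were derived from the log2 fold change and its F statistic. CPM (TMM-scaled counts normalised to library size) is given as mean ± SD over the 2 libraries of a group. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 22 lists, and again with a correlation estimated per list and with fry, which asks whether a set's genes move one way and does not compare them with other genes.

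Total counts ran from 41431776 to 53695626 per library. Replicates differed beyond sampling noise, with chi-square values per degree of freedom of 5.06 to 13.5, so none was a copy of another. The common biological coefficient of variation was 0.121. On simulated counts for 43321 genes with 200 changed, the Flp-In contrast recovered 22.4% of genes changed 1.5-fold, 46.3% of those changed 2-fold and 66.7% of those changed 4-fold. The averaged contrast recovered 44.8%, 59.7% and 92.4%, and the contrast of differences 7.46%, 26.9% and 56.1%. False calls made up 6.25%, 5.76% and 7.69% of calls.

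Except where a later choice is stated, groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Named were MEPCE, RN7SK, LARP7, HEXIM1, CDK9 and members of the 7SK and P-TEFb list called in either line. Added were the 8 genes with the largest rise and the 8 with the largest fall per knockdown contrast and their average, and 5 each for the other contrasts. These had to be called, reach a mean CPM of 5, and have groups that did not overlap. Up to 4 members per list came next, by adjusted p in the average. Outside this rule, BLM, BRCA1, EGR1, HMGCS1, MT-CO3, MYC, PALB2, POLL, SQLE and TOP1 were chosen after their values were seen. Alternatives were DESeq2 size factors, removal of mitochondrial, RN7SK, RN7SL and ribosomal RNA genes, other count filters, DESeq2 1.42.0, a replicate block, leaving out each library, a fold threshold, and fitting only the 4 libraries compared. The planned test of genes near AsiSI sites needs the hg19 sequence, which was not used here, and was not run.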

Results

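Gene expression was measured by total RNA sequencing in 2 derivatives of the U2OS osteosarcoma line after knockdown of MEPCE, in a study of MePCE at R-loops and DNA double-strand breaks. Flp-In siNC, Flp-In siMePCE, AsiSI siNC and AsiSI siMePCE had 2 libraries each. AsiSI is a restriction enzyme, which in such lines is brought into action by 4-OHT to cut DNA. AsiSI cells had received 4-OHT, whereas 4-OHT is not stated for Flp-In. Total counts were 42690551 and 41431776 in Flp-In siNC, 50409746 and 46070992 in Flp-In siMePCE, 49368255 and 53695626 in AsiSI siNC, and 44804556 and 44000840 in AsiSI siMePCE. Mitochondrial genes took 5.23% to 5.91% of counts in the siNC libraries and 8.24% to 10.55% in the siMePCE libraries.

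The targeted gene was measured first. MEPCE (ENSG00000146834, chromosome 7, 100025945 to 100031749, plus strand, hg19) had 1712 and 1676 counts in Flp-In siNC and 264 and 234 in Flp-In siMePCE. In AsiSI it had 1405 and 1542 counts under siNC and 162 and 102 under siMePCE. MEPCE was 7.85-fold lower in Flp-In (log2 fold change -2.97, SE 0.154, edgeR adjusted p = 1.72e-12) and 9.85-fold lower in AsiSI (log2 fold change -3.30, SE 0.163, adjusted p = 9.73e-13). An overlapping gene had 1.08 times the counts of MEPCE, so reads in the stretch in common cannot be assigned to either gene. RN7SK, the 7SK RNA that MePCE caps, fell from 11100 ± 286 to 2250 ± 223 CPM in Flp-In and from 7850 ± 157 to 1600 ± 3.54 CPM in AsiSI (SD, n = 2), which was 4.94-fold and 4.92-fold lower.

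**Figure D1:**
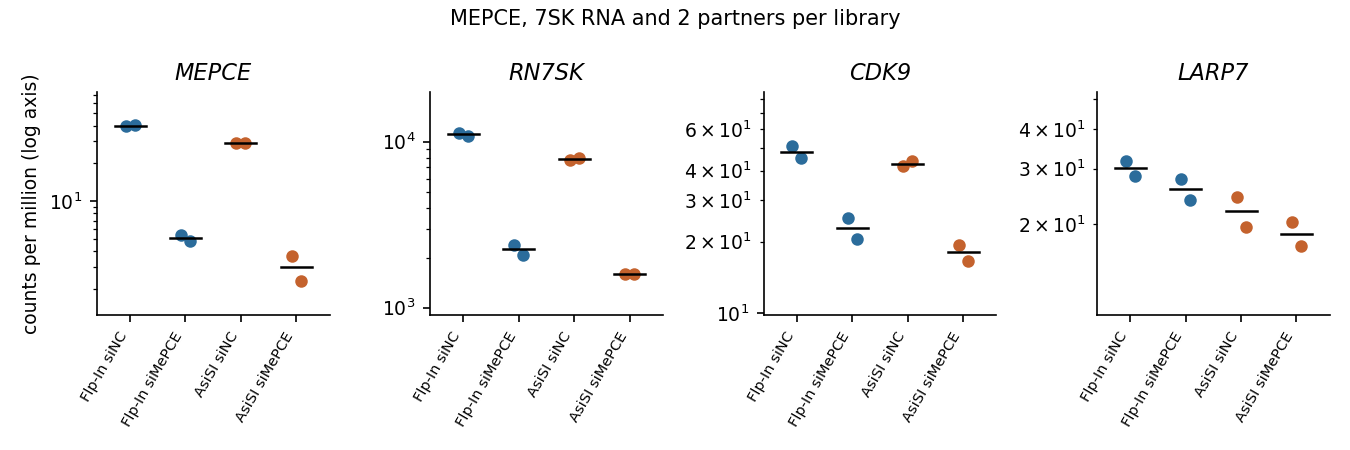
CPM (log axis) of MEPCE, RN7SK, CDK9 and LARP7 in each of the 8 libraries; points are libraries and bars are means of the 2 replicates of a group. MEPCE lay between 2.97 and 5.10 CPM on average after siMePCE and at 29.3 and 40.0 CPM after siNC.

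Around 7SK, CDK9, the kinase of P-TEFb, fell 2.11-fold in Flp-In (SE 0.118 on the log2 scale, edgeR adjusted p = 1.46e-07) and 2.37-fold in AsiSI (SE 0.119, adjusted p = 2.08e-08). The negative elongation factor subunits NELFB, NELFE and NELFCD fell in both lines, NELFE from 21.7 ± 1.15 to 13.2 ± 3.10 CPM in Flp-In and from 33.8 ± 3.56 to 19.0 ± 0.896 CPM in AsiSI (SD, n = 2). ELL, a super elongation complex subunit, rose 1.53-fold in Flp-In, AFF4 1.16-fold and SUPT4H1 1.22-fold there, while AFF1 and MLLT3 rose 1.28-fold and 1.33-fold in AsiSI. LARP7, which binds 7SK, had log2 fold changes of -0.22 (adjusted p = 0.18) and -0.24 (adjusted p = 0.164), and HEXIM1, the P-TEFb inhibitor, 0.02 (adjusted p = 0.903) and -0.18 (adjusted p = 0.204). Of the 21 members of the 7SK and P-TEFb list, 3 rose and 5 fell in Flp-In (camera adjusted p = 0.20, median log2 fold change 0.02, mean -0.18). In AsiSI 2 rose and 6 fell (camera adjusted p = 0.0194, adjusted p = 0.462 with an estimated correlation, median -0.161, mean -0.305). These counts were the same when adjusted over the list alone. Protein-coding genes as a whole had a median of -0.14 in AsiSI, with 35.1% called lower and 17% higher. The list median there thus lay near that of coding genes. Overlapping genes held at least 0.5 times the counts of LARP7, HEXIM1, NELFCD and SUPT4H1. The row overlapping RN7SK, at a count ratio of 1, was named 7SK and is a second row for the same RNA. AFF4 lost its call in Flp-In without Flp-In siNC replicate 1 (adjusted p = 0.0655), Flp-In siNC replicate 2 (0.279) or Flp-In siMePCE replicate 1 (0.359), and SUPT4H1 without Flp-In siNC replicate 1 (0.216) or Flp-In siMePCE replicate 1 (0.155). Without AsiSI siMePCE replicate 2, MLLT3 (adjusted p = 0.0514) and the list (0.0743) lost theirs in AsiSI.

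In Flp-In, MMP9, a secreted gelatinase, rose after siMePCE from 5.79 ± 0.475 to 76.8 ± 7.05 CPM (13.3-fold, log2 SE 0.156), TRAF1, a TNF receptor adaptor, from 5.35 ± 0.901 to 48.3 ± 2.90 CPM and BIRC3, an inhibitor of apoptosis, from 25.9 ± 1.11 to 194 ± 31.0 CPM (SD, n = 2). FREM1, BAAT, FAP and RIMKLA rose 7.95-fold, 6.58-fold, 6.57-fold and 6.24-fold, from 1.04, 1.5, 1.39 and 1.75 CPM. HMOX1, heme oxygenase, rose 6.08-fold (adjusted p = 0.0178), a call lost without any 1 of the 4 Flp-In libraries (adjusted p = 0.11 and 0.0862 without siNC replicates 1 and 2, 0.0592 and 0.074 without siMePCE replicates 1 and 2), with log2 fold changes of 2.47 to 2.74. IGFBP5 and HAPLN1 fell 12.9-fold and 12.6-fold, and EIF4G3, a translation initiation scaffold, from 105 ± 4.49 to 8.39 ± 0.713 CPM. HR (the hairless gene), KRT75, LMF2, COPS7A and PODXL fell 10.7-fold, 9.01-fold, 8.90-fold, 8.43-fold and 8.37-fold. KRT75 lay low in Flp-In, at 1.87 CPM under siNC and 0.204 CPM under siMePCE. It reached the mean CPM of 5 only through AsiSI siNC (47.8 CPM). EIF4G3 fell 12.5-fold, more than MEPCE itself, and off-target effects of the siRNA were not tested, so changes after siMePCE cannot be assigned to the loss of MEPCE alone. Overlapping genes held at least 0.5 times the counts of BIRC3 and IGFBP5.

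Replication-dependent histone genes fell in 29 of 33 measured members in Flp-In (30 adjusted over the list alone, median log2 fold change -1.70, camera adjusted p = 6.44e-39, and adjusted p = 0.191 with an estimated correlation). Of the G2/M and mitosis list 26 of 28 fell (26 adjusted over the list alone; camera adjusted p = 3.17e-19, adjusted p = 0.269 with an estimated correlation), among them KIF20A, CDC20, PRC1 and NUSAP1. Of the DNA replication and E2F list 30 of 35 fell (30 adjusted over the list alone; adjusted p = 2.07e-19, adjusted p = 0.269 with an estimated correlation), with RRM2, MCM7, UHRF1 and TYMS at log2 fold changes of -1.79, -1.87, -1.67 and -1.49. Homologous recombination genes fell in 19 of 31 and rose in 1 (21 and 1 adjusted over the list alone; adjusted p = 0.00231, adjusted p = 0.599 with an estimated correlation). XRCC3, RAD54L and BRIP1 fell, and BLM, a helicase, rose with a log2 fold change of 0.47. End joining genes fell in 7 of 18 and rose in 1, the same counts adjusted over the list alone (adjusted p = 0.195), PRKDC, POLL and PAXX among those lower. R-loop factors fell in 12 of 31 and rose in 6 (12 and 7 adjusted over the list alone; adjusted p = 0.345). RNASEH2A, an RNase H2 subunit, and PIF1, a helicase, had log2 fold changes of -1.29 and -2.33, whereas TOP1 rose by 0.39. Overlapping genes held at least 0.5 times the counts of KIF20A, PRC1, NUSAP1, TYMS, XRCC3, RAD54L, POLL, RNASEH2A and TOP1.

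In Flp-In the unfolded protein and integrated stress response list rose in 13 of 21 and fell in 2 (15 and 3 adjusted over the list alone; camera adjusted p = 0.000228, adjusted p = 0.307 with an estimated correlation), with DNAJB9 and DDIT3 at 1.88 and 1.35. Immediate early genes rose in 10 of 22 and fell in 3 (11 and 4 adjusted over the list alone; adjusted p = 0.00105, adjusted p = 0.384 with an estimated correlation). ATF3 and FOSB rose by 2.48 and 2.09, and EGR1 fell. For DDIT3 and FOSB, overlapping genes held 8.2 and 14.9 times their counts. NF-kB and secreted inflammatory genes rose in 6 of 19 and fell in 2, the same counts adjusted over the list alone (adjusted p = 0.000287, adjusted p = 0.269 with an estimated correlation). Heat shock and metallothionein genes fell in 13 of 14, the same count adjusted over the list alone (adjusted p = 1.27e-10, adjusted p = 0.269 with an estimated correlation), and extracellular matrix genes fell in 16 of 28 and rose in 3 (16 and 4 adjusted over the list alone; adjusted p = 3.76e-06, adjusted p = 0.191 with an estimated correlation). Ribosomal protein genes rose in 58 of 78 and fell in 3 (63 and 3 adjusted over the list alone; adjusted p = 2.46e-11, adjusted p = 0.543 with an estimated correlation). In Flp-In 17711 of 43321 genes were called by edgeR, 7849 higher and 9862 lower.

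**Figure D2:**
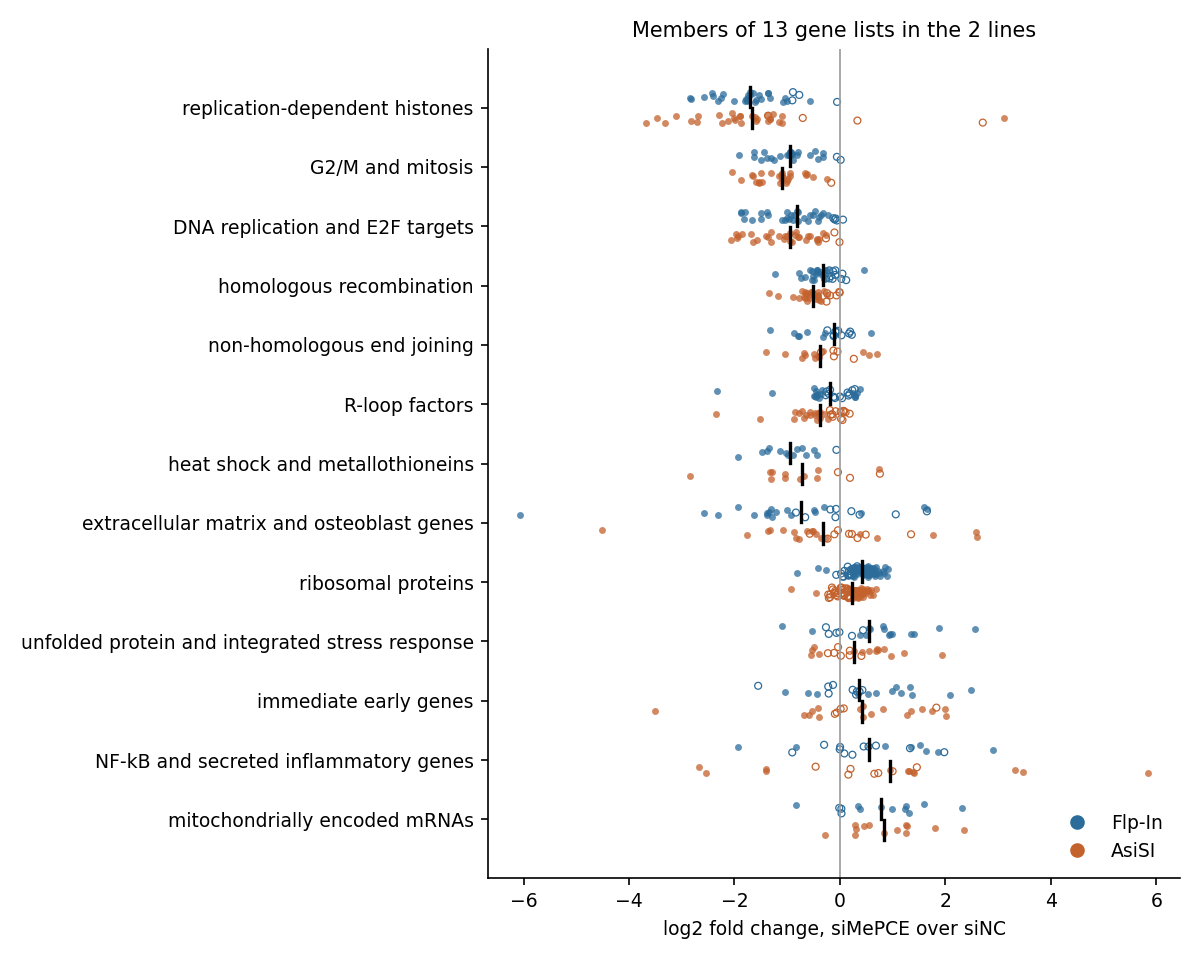
Log2 fold change, siMePCE over siNC, of each measured member of 13 gene lists in Flp-In and AsiSI; filled points passed an adjusted p of 0.05, open points did not, and black bars are list medians. Histone medians lay at -1.70 and -1.66 in the 2 lines.

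In AsiSI cells, which had received 4-OHT, BIRC3 and CXCL8, a neutrophil chemokine, rose after siMePCE 11.2-fold and 10.1-fold, CXCL8 from 62.5 ± 28.7 to 628 ± 23.6 CPM (SD, n = 2, adjusted p = 0.00102). KBTBD12, NXPH1, MTUS1-DT, DKK2, a Wnt antagonist, ODAPH and TRAF1 rose 11-fold, 9.55-fold, 8.68-fold, 7.99-fold, 7.44-fold and 7.34-fold. KRT75 fell 15.3-fold, the histone genes H2BC13, H1-1 and H3C4 12.7-fold, 11-fold and 9.91-fold, and EIF4G3, LMF2 and ABCA2 9.66-fold, 8.82-fold and 8.77-fold. Overlapping genes held at least 0.5 times the counts of BIRC3, H1-1 and H3C4. For KBTBD12 the overlapping gene MGLL held 14.7 times its counts, so the rise cannot be assigned to KBTBD12 itself. In all, 16531 genes were called by edgeR, 7273 higher and 9258 lower. More were higher than lower among genes with a mean CPM of at least 1 (7604 against 7332) and with an absolute log2 fold change of at least 1 (3873 against 3442).

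Homologous recombination genes fell in 25 of 31 members in AsiSI (25 adjusted over the list alone; camera adjusted p = 2.74e-07, adjusted p = 0.462 with an estimated correlation). BRCA1, BRCA2 and PALB2 had log2 fold changes of -0.63, -0.78 and -0.66. R-loop factors fell in 18 of 31 (18 lower and 1 higher adjusted over the list alone; adjusted p = 0.000872, adjusted p = 0.504 with an estimated correlation), FANCD2 at -0.88 and SSRP1 at -0.86 among them. End joining genes fell in 10 of 18 and rose in 3, the same counts adjusted over the list alone (adjusted p = 0.0502). Histones fell in 28 of 33 and rose in 1 (adjusted p = 4.37e-42, adjusted p = 0.305 with an estimated correlation), G2/M genes fell in 27 of 28 (adjusted p = 6.33e-29, adjusted p = 0.305 with an estimated correlation) and replication and E2F genes in 32 of 35 (33 adjusted over the list alone; adjusted p = 1.35e-27, adjusted p = 0.305 with an estimated correlation). NF-kB genes rose in 8 of 19 and fell in 4 (adjusted p = 0.00034, adjusted p = 0.381 with an estimated correlation), and immediate early genes rose in 11 of 22 and fell in 6 (adjusted p = 0.00549, adjusted p = 0.462 with an estimated correlation). The stress response list rose in 10 of 21 and fell in 4 (adjusted p = 0.0176, adjusted p = 0.462 with an estimated correlation), and heat shock genes fell in 10 of 14 and rose in 1 (adjusted p = 9.66e-08, adjusted p = 0.381 with an estimated correlation). Ribosomal protein genes rose in 37 of 78 and fell in 2 (39 and 3 adjusted over the list alone; adjusted p = 0.00034, adjusted p = 0.607 with an estimated correlation). Extracellular matrix genes fell in 14 of 28 and rose in 5 (adjusted p = 0.0871). Where no count adjusted over the list alone is given, it equalled the count over all genes.

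Averaged over both lines, siMePCE changed 22718 of 43321 genes in edgeR, 10916 higher and 11802 lower. This order turned at a mean CPM of at least 1 (9358 higher, 9082 lower) and at an absolute log2 fold change of at least 1 (5052 and 4061). It also turned among genes without an overlapping gene of at least 0.1 of their counts (3589 and 3293). Protein-coding genes were called lower in 7067 and higher in 4253 of 17341. RRM2 fell 3.67-fold, MCM7 3.73-fold and PIF1 5.04-fold (log2 SE 0.0662, 0.0707 and 0.162). PRKDC, the catalytic subunit of DNA-dependent protein kinase, fell 1.94-fold and XRCC4, a ligase partner, rose 1.57-fold. Among p53 targets 12 of 31 rose and 11 fell, the same counts adjusted over the list alone (camera adjusted p = 0.747), with CCNG1 2.42-fold higher and DDB2, XPC and BAX 2.07-fold, 1.95-fold and 1.91-fold lower. XRCC4, XPC and BAX had overlapping genes with 0.804, 1.33 and 11.4 times their counts. Fold changes of all 43321 genes correlated between the lines, with Pearson r 0.640 and Spearman rho 0.691 across genes, which are not independent replicates. The lines shared 4431 higher calls, against 1318 for independent lists, and 6956 lower calls, against 2108, and 199 genes were called in opposite directions. The 2 line contrasts share no libraries.

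**Figure D3:**
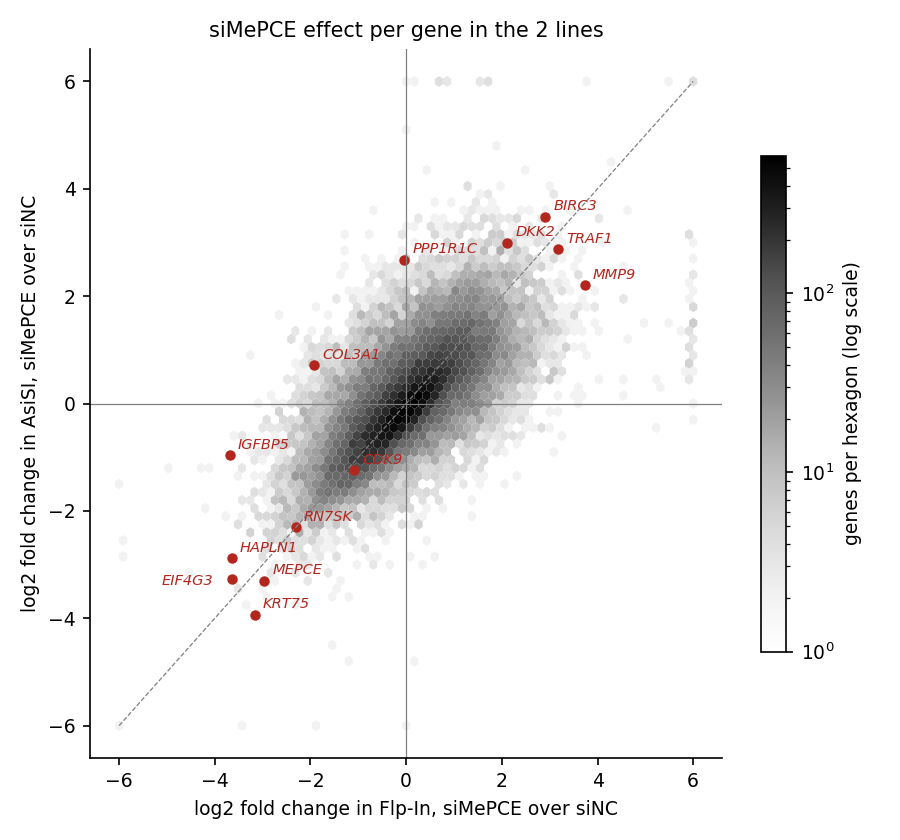
Log2 fold change of siMePCE over siNC in Flp-In (x) and AsiSI (y) for all tested genes, drawn as hexagons shaded by gene number on a log scale, with values beyond the axis range placed at its edge and named genes in red. The Pearson r across genes was 0.640, and COL3A1 and IGFBP5 lay far from the dashed line of equal change.

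The effect of siMePCE differed between the lines for 1912 genes by the test of the difference in edgeR, 1127 with a higher and 785 with a lower value in AsiSI. These were 605 and 170 at an absolute log2 difference of at least 1, and 395 and 376 among genes without an overlapping gene of at least 0.1 of their counts. IGFBP5 fell from 28 ± 1.52 to 2.17 ± 0.0308 CPM in Flp-In and measured 11.5 ± 3.47 and 5.95 ± 1.59 CPM in AsiSI, and COL3A1, a fibrillar collagen, fell from 7.50 ± 0.145 to 1.97 ± 0.491 CPM in Flp-In and rose from 6.06 ± 0.561 to 9.93 ± 0.157 CPM in AsiSI (SD, n = 2). PPP1R1C measured 15.3 and 14.9 CPM in Flp-In and rose from 2.82 to 18.1 CPM in AsiSI. CLDN1, B3GALT1, SLC8A1, FAT3 and ADAMTS1 had differences of -1.90, -1.83, -1.70, -1.61 and -1.92 on the log2 scale. Overlapping genes held at least 0.5 times the counts of IGFBP5, CLDN1, B3GALT1 and SLC8A1. MYC, chosen after its values were seen, rose 2.22-fold in Flp-In (96.8 ± 1.51 to 215 ± 13.4 CPM) and fell 1.33-fold in AsiSI (180 ± 11.8 to 136 ± 2.72 CPM; difference -1.56, SE 0.117, adjusted p = 1.12e-07). Ribosome biogenesis genes had lower effects in AsiSI for 13 of 29 members (26 adjusted over the list alone; camera adjusted p = 6.73e-18, adjusted p = 0.397 with an estimated correlation). In Flp-In 12 of them rose and 5 fell (adjusted p = 0.0547), and in AsiSI 3 rose and 16 fell (adjusted p = 0.00123, adjusted p = 0.504 with an estimated correlation), the same counts adjusted over the list alone. The number of genes with a difference was 680 without Flp-In siNC replicate 1, 1006 without Flp-In siNC replicate 2, 975 without Flp-In siMePCE replicate 1 and 1231 without Flp-In siMePCE replicate 2. Line and 4-OHT cannot be told apart in this comparison.

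**Figure D4:**
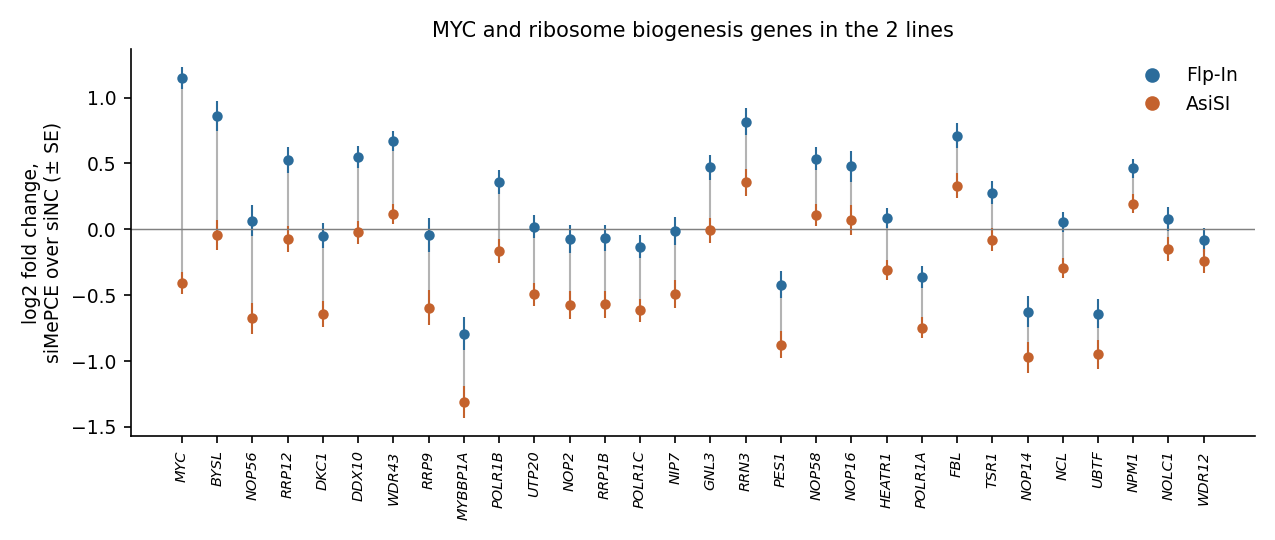
Log2 fold change of siMePCE over siNC with its SE for MYC and the 29 measured ribosome biogenesis genes in Flp-In and AsiSI. MYC lay at 1.15 in Flp-In and -0.41 in AsiSI.

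Under siNC, AsiSI cells with 4-OHT were compared with Flp-In cells, which gives the difference at lysis without knockdown of MEPCE. MAGEC1, a cancer-testis antigen, had 56.9 ± 0.973 CPM in AsiSI and 0.0472 ± 0.000876 CPM in Flp-In, and PLAAT5 had 0.0797 ± 0.00516 and 16.4 ± 0.832 CPM (SD, n = 2). SERPINB7, RFPL4A, SOX2-OT and FAP were 51.4-fold, 34.0-fold, 29.7-fold and 29.5-fold higher in AsiSI. TFPI2, HOXD10, CYP27A1 and RAC2 were 93.6-fold, 68.6-fold, 40.6-fold and 18.8-fold lower, and an overlapping gene held 23 times the counts of TFPI2. Interferon-stimulated genes were lower in 16 of 27 and higher in 1 (20 and 1 adjusted over the list alone; camera adjusted p = 3.63e-06, adjusted p = 0.136 with an estimated correlation), and immediate early genes were higher in 12 of 22 and lower in 3, the same counts adjusted over the list alone (adjusted p = 9.65e-05, adjusted p = 0.833 with an estimated correlation). Both kept their calls without each library in turn, and they were 2 of 7 lists called by camera out of 22, with 0 called with an estimated correlation (1 at an unadjusted p under 0.05). In all 12839 genes were called by edgeR, 6251 higher and 6588 lower in AsiSI, and line and 4-OHT cannot be told apart. That order of higher and lower calls turned at an absolute log2 fold change of at least 1 (2839 higher, 2379 lower). It also turned among genes without an overlapping gene of at least 0.1 of their counts (2045 and 2033). The same happened without Flp-In siNC replicate 1, Flp-In siNC replicate 2 or AsiSI siNC replicate 2.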

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

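All results here were picked out because the siMePCE effect differed between the 2 lines by a test of the difference itself, AsiSI minus Flp-In. Cell line and 4-OHT differ together between these groups, so neither can be named as the source.

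Across genes, 1912 differed by this test in edgeR, with 680, 1006, 975 and 1231 without Flp-In siNC replicates 1 and 2 and Flp-In siMePCE replicates 1 and 2. Among them 199 were called in opposite directions in the lines, 534 in the same direction, 665 in Flp-In alone and 513 in AsiSI alone. IGFBP5, PPP1R1C, HOXD10, COL3A1 and TFPI2 had log2 differences of 2.73, 2.72, 2.66, 2.64 and 2.51. ADAMTS1, CLDN1, B3GALT1, SLC8A1 and FAT3 had -1.92, -1.90, -1.83, -1.70 and -1.61. HOXD10 and TFPI2 lay below 1 CPM in AsiSI. IGFBP5, TFPI2, CLDN1, B3GALT1 and SLC8A1 had overlapping genes with at least 0.5 times their counts.

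Of the gene lists, 10 of 22 were called by camera for the difference, 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 0 by fry (3 at an unadjusted p under 0.05). Ribosome biogenesis, ribosomal proteins, R-loop factors and homologous recombination had median log2 differences of -0.478, -0.189, -0.229 and -0.203. G2/M and mitosis, DNA replication and E2F targets, and the unfolded protein and integrated stress response had -0.184, -0.154 and -0.133. Extracellular matrix, interferon-stimulated and mitochondrially encoded genes had 0.462, 0.354 and 0.104. Adjusted p values with an estimated correlation were 0.397 for ribosome biogenesis and interferon-stimulated genes, 0.234 for the matrix list and 0.772 for the others. Ribosome biogenesis and the matrix list were the 2 lists called in each of the 8 fits that left out a library. Without AsiSI siMePCE replicate 2, calls were lost for R-loop factors and interferon-stimulated genes (adjusted p = 0.0557 for both), homologous recombination (0.0731), mitochondrial mRNAs (0.264), replication and E2F (0.28) and G2/M (0.441). Without AsiSI siNC replicate 1 they were lost for recombination (adjusted p = 0.107), replication and E2F (0.112) and G2/M (0.112). Without Flp-In siMePCE replicate 1 they were lost for interferon-stimulated genes (adjusted p = 0.0734), ribosomal proteins (0.0763), replication and E2F (0.219), G2/M (0.291) and the stress response (0.291). The stress response and interferon-stimulated genes lost them without Flp-In siNC replicate 1 (adjusted p = 0.113 and 0.107) or AsiSI siNC replicate 2 (0.124 and 0.0919), and the stress response without AsiSI siMePCE replicate 1 (0.0754). Mitochondrial mRNAs lost theirs without Flp-In siNC replicate 2 (adjusted p = 0.143) or Flp-In siMePCE replicate 2 (0.382), and replication and E2F without Flp-In siNC replicate 2 (0.0646).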

How the results depend on the processing

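The restriction to genes without an overlapping gene of at least 0.1 of their counts was chosen after seeing the data. It tested 12108 genes and called 5466 in Flp-In, 5068 in AsiSI, 6882 in the average, 771 for the difference between lines and 4078 between the lines under siNC; the counts are lower because fewer genes were tested, and the called shares were 45.14%, 41.86%, 56.84%, 6.37% and 33.68% against 40.88%, 38.16%, 52.44%, 4.41% and 29.64% of all genes. A log2 fold change of at least 1 left 8341, 7315, 9113, 775 and 5218 genes in the same order, by its construction. DESeq2 size factors, removal of mitochondrial, RN7SK, RN7SL and ribosomal RNA genes, other count filters and the DESeq2 Wald test kept the 5 counts within 1.5 times, as did the 4 compared libraries alone for Flp-In, AsiSI and the lines under siNC, where this was run. DESeq2 called 91.44% to 93.88% of the same genes in the same direction and 0 in the opposite one (edgeR with size factors 97.88% to 99.69%, also 0 opposite). The median shift between both scalings was 0.023.

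With a replicate block the difference between lines had 3089 genes, and the cause was not tested. End joining in AsiSI (camera adjusted p = 0.047) and ribosome biogenesis in Flp-In (camera adjusted p = 0.0491) were called with the block, but not without it. The same held for AFF1 in Flp-In (edgeR adjusted p = 0.04009). Gene counts also rose with the block in Flp-In (19056), AsiSI (17958), the average (23680) and between the lines under siNC (14200). Deviations from group means correlated weakly and positively between groups, by 0.0427 to 0.155. A small component shared by replicate number is therefore not excluded.

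Leaving out a library leaves a group with 1 library, assumed to vary like the other groups. Calls then ran from 12712 to 18402 in Flp-In, 12993 to 16299 in AsiSI, 19775 to 22259 in the average and 8679 to 13543 under siNC. For the difference between lines they ran from 680 to 1884, with 680, 1006, 975 and 1231 without Flp-In siNC replicates 1 and 2 and Flp-In siMePCE replicates 1 and 2; without single AsiSI libraries it was 1439 to 1884, and the cause was not tested. MEPCE ran from -3.047 to -2.902 in Flp-In and -3.671 to -3.004 in AsiSI. The correlation of the lines ran from 0.5248 to 0.598 and was 0.849 at a mean CPM of at least 5; the cause was not tested.

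With an estimated correlation 0 lists were called in Flp-In, 0 in AsiSI, 0 in the average and 0 for the difference (2, 2, 3 and 1 at an unadjusted p under 0.05), against 14, 16, 14 and 10 with camera's preset and 15, 18, 19 and 0 with fry (3 unadjusted for the difference). Lists called for the difference ran from 4 (without AsiSI siMePCE replicate 2) to 12, with 6 without Flp-In siMePCE replicate 1.

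Of 188 single-gene results, 176 kept direction and side of the threshold whichever library was left out, 186 with size factors and 187 with DESeq2. HEXIM1 in Flp-In turned to -0.1273 without Flp-In siMePCE replicate 1 (adjusted p = 0.4461), and SUPT4H1 in AsiSI to 0.07472 without AsiSI siNC replicate 2 (adjusted p = 0.6009); neither had been called, and the cause was not tested. LARP7 in the average lost its call with size factors (adjusted p = 0.0615), DESeq2 (adjusted p = 0.07278) and without Flp-In siNC replicate 1 (0.16), AsiSI siNC replicate 1 (0.211), Flp-In siMePCE replicate 2 (0.169) or AsiSI siMePCE replicate 2 (0.158). AFF4 in the average lost it without Flp-In siMePCE replicate 1 (adjusted p = 0.169), AsiSI siMePCE replicate 1 (0.153), Flp-In siNC replicate 2 (0.129) or AsiSI siNC replicate 2 (0.075). AFF4, SUPT4H1 and HMOX1 in Flp-In, MLLT3 in AsiSI and GRHL2 kept their calls with size factors and DESeq2. At the depth and group size of these libraries, 7.46% of simulated 1.5-fold differences between lines were recovered, so small differences are largely out of reach; depth and replicate number were not varied. The test of genes near AsiSI sites and its alternatives was not run.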

Other observations

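Cholesterol biosynthesis genes fell in 13 of 24 and rose in 4 in the averaged contrast (14 and 4 adjusted over the list alone; camera adjusted p = 0.00805, adjusted p = 0.588 with an estimated correlation). The list was called in Flp-In (11 of 24 lower, 3 higher; adjusted p = 0.00428, adjusted p = 0.65 with an estimated correlation; 12 and 3 adjusted over the list alone) and in AsiSI (11 and 3; adjusted p = 0.0273, adjusted p = 0.607 with an estimated correlation), there not without AsiSI siNC replicate 1 (0.38) or AsiSI siMePCE replicate 2 (0.102). FDPS, LSS and EBP fell 2.37-fold, 2.18-fold and 1.74-fold, whereas HMGCS1 and SQLE rose by 0.58 and 0.51 on the log2 scale in Flp-In. Hypoxia and glycolysis genes were called as a list in AsiSI (7 of 19 higher, 3 lower; adjusted p = 0.032, adjusted p = 0.462 with an estimated correlation), a call lost without AsiSI siNC replicate 1 (0.075), and neither in Flp-In (7 and 4; adjusted p = 0.132) nor in the average (7 and 3; adjusted p = 0.0574), where PDK1 was 2.10-fold and KDM3A 1.87-fold higher and EGLN3 1.78-fold lower. Interferon-stimulated genes were called as a list in Flp-In (14 of 27 lower, 3 higher; adjusted p = 0.0135, adjusted p = 0.269 with an estimated correlation), a call kept without each library in turn, and not in AsiSI (6 and 2; adjusted p = 0.365). In the average the list was not called either (12 and 3, 12 and 4 adjusted over the list alone; adjusted p = 0.0817), with IFI44 5.61-fold and OAS3 2.33-fold lower. Short structured RNAs rose in 9 of 11 (adjusted p = 8.32e-05, adjusted p = 0.384 with an estimated correlation), SCARNA6 and SCARNA5 3.61-fold and 2.49-fold. Epithelial markers rose in 4 of 8 and fell in 1 (adjusted p = 0.133), with CLDN4 2.99-fold higher, and blood and endothelial markers rose in 4 of 8 and fell in 1 (adjusted p = 0.535). FDPS, LSS, EBP, PDK1, EGLN3, OAS3, SCARNA6, SCARNA5 and GRHL2 had overlapping genes with at least 0.5 times their counts. GRHL2, 1.78-fold higher, lost its call without Flp-In siNC replicate 1 (adjusted p = 0.0937), AsiSI siNC replicate 1 (0.0771) or AsiSI siMePCE replicate 2 (0.105). Where no count adjusted over the list alone is given, it equalled the count over all genes.

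In the tests below, those on olfactory receptor genes, other short genes, the E2F list and MT-CO3 were chosen after the result was seen. For the averaged contrast, 34 splits of the 8 libraries into 4 and 4 could be fitted with the cell line as a term. Of these 1, the real one, called as many genes in edgeR. The real split called 20471 and the highest of the others 0, with up to 3918 at an unadjusted p under 0.05. In the other splits the siMePCE effect enters the residual spread, which lowers their calls. Splits are few and separate cultures are not stated, so this test cannot exclude chance.

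Genes typed as lincRNA were called higher in 1567 and lower in 682 of 4416, with a median log2 fold change of 0.391 against -0.118 for protein-coding genes. Genomic DNA in the siMePCE libraries would raise olfactory receptor genes. The summed CPM of 273 of them without an overlapping gene of at least 0.1 of their counts changed by only -0.0216 (SD 0.0873). Reads shared with overlapping genes would leave little change in lincRNA rows without such a gene, but their median was 0.528 over 1346 rows. Genes typed as antisense were called higher in 853 and lower in 1362 of 4282, with a median of -0.106. Medians were positive for snoRNA (0.619), snRNA (0.417), processed pseudogenes (0.141) and genes without a type (0.295). Positive medians were thus not particular to lincRNA rows. Antisense rows can hold reads of genes on the other strand, because counts appear to ignore strand. Their median therefore cannot show whether antisense RNAs rose. A rise of lincRNA after MEPCE knockdown may be biological, as a hypothesis found and tested on the same data.

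Histone genes fell with a median log2 fold change of -1.69. A loss of short RNAs would lower other short genes, but 209 spanning up to 1 kb had a median of 0.0314 (SE 0.0728). Of these, 167 had an overlapping gene of at least 0.1 of their counts. The 21 nuclear ones without such a gene were therefore read too, at -0.0268 (SE 0.161). This argues against a loss of short RNAs as the whole cause. A part stays open, since protein-coding genes had a median of -0.448 at spans up to 5 kb and 0.113 at spans over 200 kb. Reads moving between near-identical copies would leave their sum unchanged, but the summed CPM of the histone list fell by 1.69 on the log2 scale. Fewer cells in S phase is a candidate explanation, with 31 of 35 replication and E2F genes lower (median -0.861), but 26 of 28 G2/M and mitosis genes were lower too (median -1.02), so this is not particular to S phase, and cell cycle phase was not measured here.

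Mitochondrial mRNAs rose in 12 of 13 and fell in 1, the same counts adjusted over the list alone (camera adjusted p = 4.43e-14, adjusted p = 0.247 with an estimated correlation), MT-ND6 5.08-fold and MT-ND5 3.24-fold. A larger mitochondrial share raising all of them alike would lower none, but MT-CO3 fell although another gene overlaps it (log2 fold change -0.552, SE 0.0541). It fell by 0.824 in Flp-In and by 0.28 in AsiSI, and by 0.193 in AsiSI without AsiSI siMePCE replicate 1. MT-CO3 was picked after its fall was seen. The mRNAs thus did not change alike, but a general rise with a further change of single genes is not excluded. More transcript from the light strand, which encodes MT-ND6, would raise light-strand tRNA genes above heavy-strand ones. Their medians differed by -0.014 over 8 and 14 genes (permutation p = 0.581, one-sided, 100000 resamples; light-strand MT-TE rose by 2.17 and the other 7 by 0.66 to 1.03), which met the criterion written beforehand against that explanation, a difference at or below 0. A margin beyond chance placement of the strands was applied only after the value was seen, and with it the explanation cannot be told apart, because -0.014 lies within that chance and counts without strand mix both transcripts.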
